A study of Mus musculus with 4 samples.

How the data were processed

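Small RNA of sorted Kit-positive cells was sequenced in 4 libraries, 1 each for jejunum and colon of ob/+ and ob/ob mice. Per the labels' protocols, whole jejunal or colonic tissue was dissociated, GFP-positive cells were sorted, RNA was extracted with a mirVana kit, material of the same genotype was pooled (15 each) and libraries followed standard Illumina protocols. Columns named for the small intestine were matched to the jejunal libraries.

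The deposited tables hold 982 entries, 104 of them named as hairpins and 142 with neither an arm suffix nor a hairpin name. Per the file headers, the authors removed 3' adapters, set aside reads under 15 nt and assigned mappable reads to miRBase 20 miRNAs on mouse genome mm9. The aligner, the counting program and the scaling rule are not given in the sources used here. The deposited raw values are estimated counts: of the values above 0, between 87.7% and 89.8% per library are whole (within 1e-06), and the rest are fractional. Where the fractions come from was not tested. The authors' normalized values are a signal equal to the raw counts times 1 factor per library (1.05, 1.00, 0.661 and 1.45 in the order jejunum ob/+, jejunum ob/ob, colon ob/+, colon ob/ob). The authors' deposited table also gives the ratio of ob/ob over ob/+ for 235 miRNAs, in which 2 zeros had been replaced by 0.01. The deposited statistics sheet gives other values, the read numbers at each step.

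Raw reads numbered 13237163, 19938908, 11844268 and 11381897 in that order, of which 48.0%, 58.7%, 35.9% and 36.0% had no adapter. Mappable reads numbered 2068523, 3511669, 2727038 and 2511371, and miRNAs with at least 1 count 614, 697, 627 and 600. Hairpin-named entries took 0.302%, 0.518%, 0.226% and 0.596% of the miRNA counts. Intervals and floors (3 counts) cover counting error only, since reads without molecular identifiers are not independent molecules.

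Estimated counts were rounded to whole numbers and scaled by trimmed mean of M-values (TMM) factors of 0.940, 0.973, 0.920 and 1.19. The 322 entries with a mean of at least 10 CPM over the 4 libraries were tested. Ratios within a tissue or genotype used log2 CPM with a prior count of 2 and an exact conditional binomial 95% interval, with no test. The genotype effect over both tissues was tested with edgeR's quasi-likelihood test with tissue as a term, and the tissue effect with genotype as a term, with Benjamini-Hochberg adjustment over the 322 and a threshold of 0.05. The residual had 1 degree of freedom, the prior degrees of freedom were 3.70 and the common biological coefficient of variation was 17.3%. Each SE given with a log2 change is its absolute value divided by the square root of the test's F statistic. It is not a spread between replicates. The fits were tested on simulated counts: over both tissues 15 of 28 miRNAs changed 2-fold, 20 of 21 changed 4-fold and 29 of 29 changed 8-fold were recovered among 327 tested, with 0 false calls.

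The 26 miRNA lists, the groups, the tests and the rule for named miRNAs were fixed before the data were examined. The lists were the miR-10 pair, Hox-encoded, Kit-targeting, smooth and striated muscle, fibroblast, epithelium, leukocyte, erythroid, endothelium, neuron and glia, endocrine, liver, let-7, miR-17-92, miR-15/16, miR-29, miR-30, miR-34 and miR-449, miR-23/27/24, miR-181, miR-99, miR-100 and miR-125, miR-183 cluster, insulin and lipid metabolism, inflammation and stress, Dlk1-Dio3 and Sfmbt2 lists. Named were the 5 most abundant miRNAs, the miR-10 pair, the 10 with the largest ratio in each direction per tissue among those at least 2-fold different and at 100 CPM or more in 1 of the 2 libraries, the 10 with the smallest p in each direction per test (or, with no call, the 10 that differed most in the same direction in both pairs), up to 4 abundant members per list, and up to 5 per direction with 2-fold differences in opposite directions between tissues, of which there were 0. The text gives a choice of these, and marks others as named after their values were seen.

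Alternatives fixed beforehand were library totals without TMM, median-of-ratios factors, no abundance filter, a 100 CPM filter, prior counts of 0.5 and 5, thresholds of 1.5-fold and 4-fold, no term for the other factor, DESeq2 and limma-voom. Scaling to mappable reads, the authors' factors and leaving out hairpin entries were added after the data were seen, as were fits with no term for the other factor and 1 library left out (1 residual degree of freedom, factors computed again, the same 322 entries). On simulated counts these recovered 14 to 18 of 20 miRNAs changed 4-fold by genotype and 7 to 14 of 21 by tissue, with 0 to 2 false calls, and 0 calls where no change was simulated. Each simulation changed 1 factor only, so the other factor added no spread, unlike in the data. Gene names, neighbours and chromosomes came from a RefSeq table of assembly GRCm38.p6, in which 319 of the 322 entries matched a miRNA gene. No coordinates are given, since the deposited files use mm9. Permutation tests used 100000 shuffles and were one-sided, and were tested on simulated data. With no shared change, p was under 0.05 in 9% of 100 simulated data sets for clusters and 5% for arms. A larger run of 500, added after that result, gave 5.2% and 4.8%. With a shared change it was 100% for both. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.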

Results

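Interstitial cells of Cajal (ICC) are the pacemaker cells of the gut muscle layer and carry the receptor tyrosine kinase Kit. MicroRNAs (miRNAs) were sequenced from Kit-positive ICC, sorted by a copGFP reporter from the jejunum or the colon of C57BL/6 mice aged 11 to 20 weeks. Mice homozygous for the Lep ob mutation (ob/ob), which lack functional leptin and which the labels call diabetic, were compared with heterozygous mice (ob/+), which the labels call healthy. There were 4 libraries, 1 for each combination of tissue and genotype, and each was made from a pool (15 each, per the labels). Values within a tissue therefore have no replicates, and the intervals and floors given cover counting error only.

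The ob/+ jejunum library held 466335 miRNA counts, the ob/ob jejunum library 433201, the ob/+ colon library 716476 and the ob/ob colon library 267077. In that order, 1 count was worth 2.28, 2.37, 1.52 and 3.15 CPM (normalised counts, scaled to an equal library total), and a count of 0 allowed up to 6.84, 7.12, 4.55 and 9.45 CPM. MiRNA counts made up 22.5% of the mappable reads of the ob/+ jejunum library (exact binomial 95% interval 22.5 to 22.6) and 12.3% of those of the ob/ob jejunum library (12.3 to 12.4). In colon the shares were 26.3% (26.2 to 26.3) in ob/+ and 10.6% (10.6 to 10.7) in ob/ob. The ratios reported here are relative to the other miRNAs of a library; scaled to mappable reads, the median ratio of ob/ob over ob/+ shifted by -0.78 in jejunum and -0.86 in colon (log2).

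Few miRNAs dominated the sorted cells, and the 10 most abundant took between 73.5% and 76.2% of the counts of each library. miR-145a-5p, a smooth muscle miRNA, took 12.4% of the counts in ob/+ jejunum, 19.0% in ob/ob jejunum, 9.24% in ob/+ colon and 16.1% in ob/ob colon. miR-143-3p, made from the same transcript, took 10.6%, 13.6%, 9.65% and 11.9%. miR-10b-5p was among the most abundant miRNAs of the ob/+ libraries, with 15.2% of the counts in jejunum (exact binomial 95% interval 15.1 to 15.3) and 15.8% in colon (15.7 to 15.9). In ob/ob its share was 1.34% in jejunum (1.31 to 1.38) and 1.07% in colon (1.03 to 1.11). Its near-identical relative miR-10a-5p took between 8.91% and 12.9% of the counts, and miR-125b-5p between 6.25% and 9.64%.

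The main comparison asked which miRNAs of ICC differed between leptin-deficient and heterozygous mice, over both tissues at once. The miRNAs encoded in the Hox gene clusters, which set positional identity along the body axis, included miR-196b-5p, with the largest fall of the 33 called, and miR-10b-5p. miR-10b-5p fell 15.0-fold (log2 change -3.90 ± 0.23 SE, back-calculated from the F statistic, adjusted p = 0.00350). It went from 161360 to 13783 CPM in jejunum and from 172162 to 8981 CPM in colon. miR-196b-5p fell 123-fold (-6.95 ± 0.37, adjusted p = 0.00350), from 1036 counts to 5 in jejunum and from 1827 to 10 in colon. miR-196a-5p fell by 3.69 ± 0.48 on the log2 scale (adjusted p = 0.0186) and miR-10b-3p, the other arm of the miR-10b hairpin, by 3.09 ± 0.32 (adjusted p = 0.0126). miR-615-3p rose by 2.74 ± 0.55 (adjusted p = 0.0368), from 4 counts to 60 in jejunum and from 15 to 28 in colon. With 1 library left out and no tissue term, the log2 change of miR-615-3p was 3.64 without the ob/+ colon library. Without the ob/ob jejunum library that of miR-196b-5p was -6.34 and that of miR-196a-5p -3.10, and without the ob/ob colon library -7.60 and -4.32. miR-10a-5p did not pass (0.13 ± 0.21, adjusted p = 0.666); its ratio was 0.49 in jejunum, or -0.33 scaled to mappable reads, and -0.22 in colon, or 0.15 with library totals alone. miR-10a-3p did not pass either (0.52 ± 0.40, adjusted p = 0.382), with ratios of 1.10 in jejunum and -0.05 in colon. Of the 7 Hox-encoded arms tested, 4 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone. The miR-10 pair by itself had 2 of 4 arms that fell, also 2 adjusted over the list alone. That list was picked with knowledge of the authors' work on miR-10b and is not independent evidence. Its 4 arms are also among the 7 Hox-encoded arms, so the Hox counts are not separate from it. In the GRCm38.p6 annotation Mir10b lies within Hoxd3 and Hoxd4, Mir196b between Hoxa9 and Hoxa10, Mir10a within Hoxb3 and Mir615 within Hoxc5. The same ob/ob libraries held less of the fibroblast miRNAs (963 and 888 CPM in jejunum and colon, against 4812 and 5001 in ob/+) and of the epithelial miRNAs (420 and 334 CPM, against 2277 and 1085).

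All 4 arms tested from the fibroblast and mesenchyme list fell, also adjusted over the list alone. miR-199a-5p fell 5.44-fold (log2 change -2.44 ± 0.21, adjusted p = 0.0126), from 975 counts to 173 in jejunum and from 1508 to 133 in colon. miR-214-3p fell 8.96-fold (-3.16 ± 0.32, adjusted p = 0.0126). miR-199b-3p and miR-199b-5p each fell by 2.30 on the log2 scale (adjusted p = 0.0126 and 0.0368), and the call of miR-199b-5p was lost in DESeq2 (adjusted p = 0.0691, range over the alternatives 2.08e-07 to 0.125). With no tissue term the log2 change of miR-199b-5p was -1.70 without the ob/ob jejunum library and -2.96 without the ob/ob colon library.

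Epithelial miRNAs, markers of the gut mucosa that a Kit sort is not aimed at, also fell: 5 of 8 arms tested, or 6 adjusted over the list alone. miR-200b-3p fell 15.6-fold (log2 change -3.96 ± 0.56, adjusted p = 0.0190), from 302 counts to 9 in jejunum and from 180 to 12 in colon. miR-192-5p fell 6.03-fold (-2.59 ± 0.37, adjusted p = 0.0190). These falls were smaller without the ob/+ jejunum library and with no tissue term. The log2 changes were then -3.11 for miR-200b-3p, -2.33 for miR-200a-3p (-3.29 with all libraries), -1.84 for miR-200c-3p (-2.62) and -1.90 for miR-192-5p. That of miR-200b-3p was -4.57 without the ob/+ colon library, -3.65 without the ob/ob jejunum library and -4.34 without the ob/ob colon library. miR-194-5p and miR-215-5p had log2 changes of -0.96 and -0.53 and did not pass (adjusted p = 0.0962 and 0.293); the colon ratio of miR-215-5p turned from -0.13 to 0.22 with library totals alone. All 3 miRNAs of the cluster of miR-183, miR-96 and miR-182, known from sensory and epithelial cells, fell, also adjusted over the list alone. miR-182-5p went from 62 counts to 9 in jejunum and was at least 7.55-fold lower in colon, where 47 counts stood against 0. The median log2 ratio of this cluster was -2.72 in jejunum and -2.37 in colon, or -1.94 in colon with members at 0 counts set to their bound. Without the ob/+ jejunum library and with no tissue term, the calls of miR-182-5p (-2.40, adjusted p = 0.0744, against -3.31 with all libraries) and miR-96-5p (-1.58, 0.299, against -3.38) were lost, and miR-183-5p went from -3.91 to -2.25. Without the ob/+ colon library miR-183-5p stood at -4.62, and without the ob/ob colon library miR-182-5p and miR-96-5p stood at -2.16 and -2.26. Without the ob/ob jejunum library 0 ob/ob counts of these 2 were left, which gives no finite fold. The hepatocyte miRNA miR-122-5p fell 11.6-fold (-3.53 ± 0.45, adjusted p = 0.0183), from 434 to 23.7 CPM in jejunum and from 190 to 28.3 CPM in colon, with a log2 change of -2.73 without the ob/+ jejunum library and -4.06 without the ob/+ colon library. The endocrine miRNA miR-375-3p fell by 2.90 ± 0.59 (adjusted p = 0.0368, but 0.0691 in DESeq2, range over the alternatives 1.27e-07 to 0.135). Its log2 change was -1.52 without the ob/+ jejunum library, where the call was lost (adjusted p = 0.0991), and -3.57 without the ob/+ colon library. miR-7a-5p and miR-7b-5p had log2 changes of 0.70 and 0.79 (adjusted p = 0.0962 and 0.0854), so that 1 of 3 endocrine arms fell, and 1 fell and 2 rose adjusted over the list alone. The endocrine median ratio was 0.53 in jejunum and 0.86 in colon, and turned to -0.29 and -0.07 scaled to mappable reads and to -0.04 and -0.09 with no abundance filter.

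**Figure D1:**
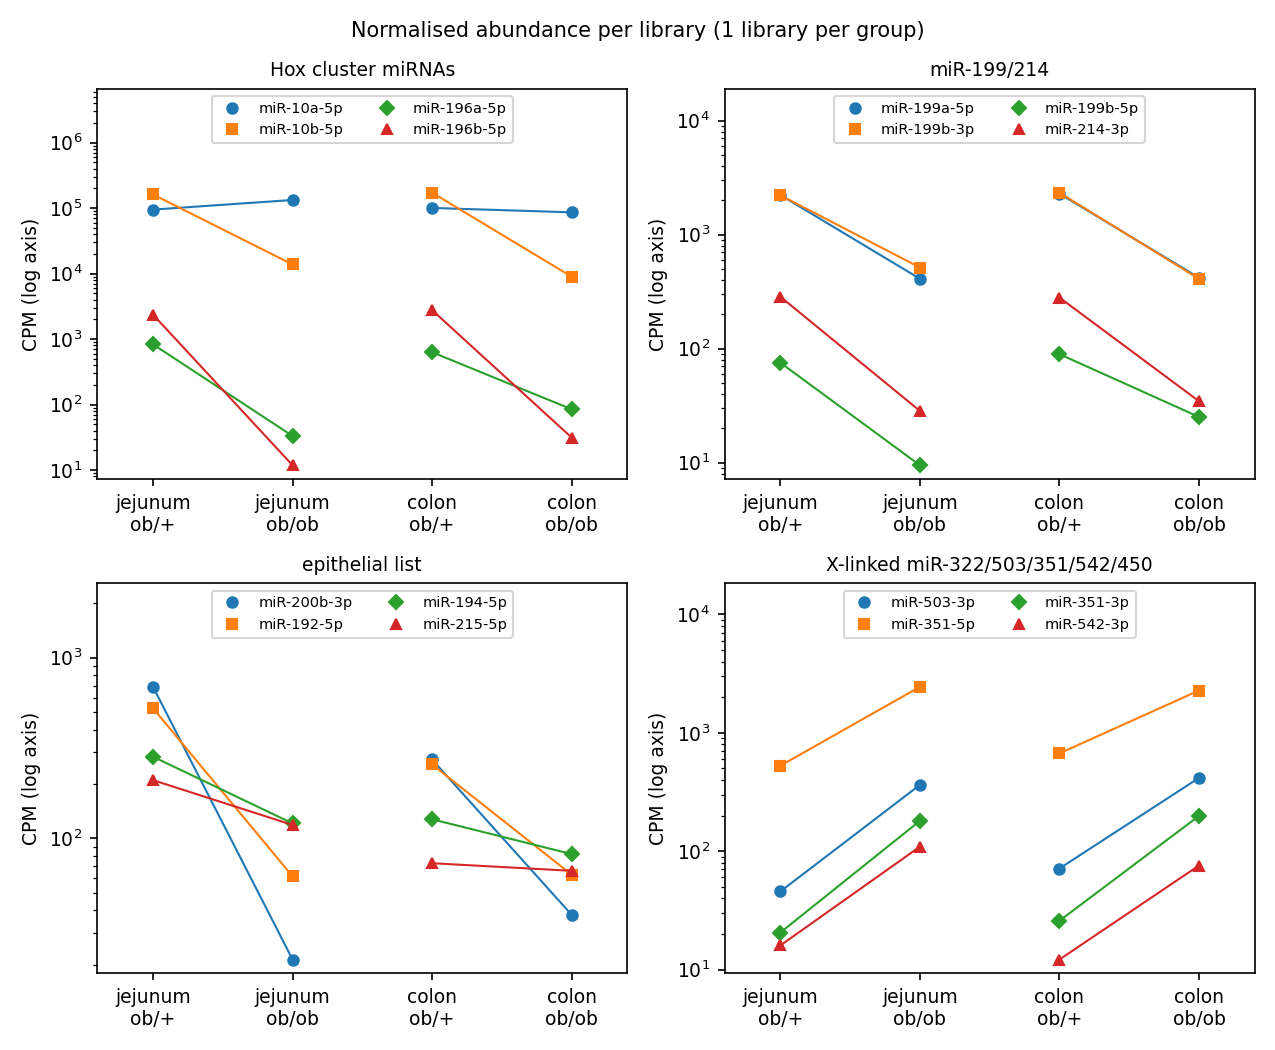
CPM (log axis) of 4 miRNAs from each of 4 groups in the 4 libraries, 1 point per library, with lines joining the ob/+ and ob/ob libraries of a tissue. miR-10b-5p goes from 161360 to 13783 CPM in jejunum and from 172162 to 8981 CPM in colon, while miR-351-5p goes from 527 to 2444 CPM and from 669 to 2277 CPM.

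Among miRNAs described as targeting Kit mRNA, miR-221-3p and miR-222-3p fell by 1.57 ± 0.23 and 1.80 ± 0.28 on the log2 scale (adjusted p = 0.0190 and 0.0207). The other 5 of 7 arms did not pass, among them miR-218-5p (1.48 ± 0.35, adjusted p = 0.0508); adjusted over the list alone, 2 fell and 1 rose. miR-99a-5p fell 2.82-fold (adjusted p = 0.0126), the 1 call among 8 arms of the miR-99, miR-100 and miR-125 families, against 2 falls adjusted over the list alone. miR-23a-3p fell by 1.09 ± 0.17 (adjusted p = 0.0207), the 1 call among 8 arms of the miR-23/27/24 clusters, also 1 over the list alone. miR-574-3p fell by 2.99 ± 0.33 (adjusted p = 0.0126). Of 7 inflammation and stress arms 1 fell, miR-132-3p (-1.30 ± 0.30, adjusted p = 0.0495, but 0.125 in DESeq2, range over the alternatives 1.02e-06 to 0.162), and adjusted over the list alone 1 fell and 1 rose.

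The imprinted Dlk1-Dio3 region, a large miRNA locus active in fetal growth, had 40 arms tested. Its median log2 ratio was -0.87 in jejunum and -0.77 in colon, at percentiles 0.01 and 0.045 among 10000 random lists matched on abundance, a description of these libraries. Arms of the same locus can move together, which random lists do not copy, so these percentiles are no test. The epithelial list stood at percentiles 0.01 and 0.06 and the Hox list at 0.03 and 0. Of the Dlk1-Dio3 arms, 16 were at least 2-fold lower and 0 higher in jejunum, and 11 and 0 in colon. Over both tissues 3 fell, miR-127-3p (-1.09 ± 0.18, adjusted p = 0.0259), miR-434-3p (-1.14 ± 0.23, adjusted p = 0.0368) and miR-411-3p (-2.05 ± 0.37, adjusted p = 0.0333), the last named after its values were seen. Adjusted over the list alone, edgeR called 0 of the 40. The fibroblast markers fell in the same ob/ob libraries (median -2.48 in jejunum and -2.47 in colon), as did the epithelial markers (-2.76 and -1.82, or -1.03 and -0.76 with no filter and -2.10 and -1.28 at 100 CPM), and a change in the cell mix was not separated from a change in this region.

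Of the miRNAs that rose, the clearest group was the X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450, located between Hprt and Plac1 in GRCm38.p6. This group was formed after its values were seen. All 9 of its arms tested were at least 2-fold higher in both tissues, and 7 passed over both tissues; scaled to mappable reads, 8 of the 9 were at least 2-fold higher in jejunum and 4 in colon. The median log2 ratio was 2.48 in jejunum, or 2.17 with members at 0 counts set to their bound, and 1.76 in colon. Scaled to mappable reads the medians were 1.75 and 0.94. miR-503-3p rose 6.67-fold (log2 change 2.74 ± 0.29, adjusted p = 0.0126), miR-351-5p 3.96-fold (1.99 ± 0.23, adjusted p = 0.0126) and miR-351-3p 8.07-fold (3.01 ± 0.33, adjusted p = 0.0126). miR-542-3p rose from 7 counts to 46 in jejunum and from 8 to 24 in colon (adjusted p = 0.0190), and miR-450a-5p by 1.80 ± 0.34 (adjusted p = 0.0344). miR-322, a member of the cell cycle restraining miR-15/16 family, gave the 2 calls among 6 arms of that family. miR-322-3p rose by 1.51 ± 0.33 (adjusted p = 0.0414) and miR-322-5p, named after its values were seen, by 2.29 ± 0.52 (adjusted p = 0.0472), with adjusted p = 0.0717 and 0.0619 scaled to mappable reads. Without the ob/+ colon library and with no tissue term the call of miR-322-5p was lost (1.95, adjusted p = 0.0759). Over the alternatives the adjusted p ranged from 2.55e-06 to 0.162 for miR-322-3p and from 0.000300 to 0.145 for miR-322-5p. Adjusted over the list alone 2 rose and 1 fell. The family's median ratio was 0.10 in jejunum, or -0.66 scaled to mappable reads and -0.02 with the authors' factors, and -0.09 in colon, or 0.27 with library totals alone.

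Outside this cluster 17 miRNAs or hairpins rose; lower-case mir marks an entry the deposited table names after the hairpin. mir-6240 rose by 1.82 ± 0.21 (adjusted p = 0.0126), from 327 counts to 1027 in jejunum and from 311 to 571 in colon. miR-3470b and mir-1954 rose by 2.16 ± 0.29 and 2.28 ± 0.31 (adjusted p = 0.0190 for each). miR-3470a and miR-3470b are near-identical, and how counts were split between them is uncertain. miR-7035-5p, miR-3472 and miR-1194 rose by 3.01, 2.30 and 2.11 (adjusted p = 0.0207, 0.0242 and 0.0313) on at most 36 counts in a library; the jejunum ratio of miR-7035-5p, at 2 counts in ob/+, was 2.60 (counting interval 1.42 to 6.59). miR-30e-5p rose by 1.15 ± 0.22 (adjusted p = 0.0360), the 1 call among 10 arms of the miR-30 family, also 1 over the list alone; scaled to mappable reads its adjusted p was 0.388 (range over the alternatives 2.70e-07 to 0.388) and its colon ratio turned to -0.05. The mappable reads outside miRNAs made up 87.7% and 89.4% in the ob/ob jejunum and colon libraries, against 77.5% and 73.7% in ob/+.

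Of 6 smooth and striated muscle arms 0 passed in edgeR's test over all miRNAs, and 2 were higher adjusted over the list alone. miR-145a-5p had a log2 change of 0.50 ± 0.12 (adjusted p = 0.0551). The list's median ratio was 0.81 in jejunum and 0.45 in colon, and turned to -0.01 and -0.47 scaled to mappable reads. Of 7 leukocyte arms 1 rose, miR-342-5p (1.53 ± 0.33, adjusted p = 0.0415, but 0.217 scaled to mappable reads, range over the alternatives 0.000641 to 0.217), and 3 rose adjusted over the list alone. miR-146a-5p, induced by NF-kappaB, had a log2 change of 0.97 ± 0.26 (adjusted p = 0.0643). The leukocyte list summed to 1723 and 3777 CPM in ob/+ and ob/ob jejunum and to 1786 and 2733 CPM in colon, where its median ratio turned from 0.62 to -0.31 scaled to mappable reads.

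No arm of the let-7 (14 tested), miR-17-92 (8), miR-29 (5), miR-181 (6), miR-34 and miR-449 (3), endothelial (2), erythroid (2), neuronal and glial (7) and Sfmbt2 (3) lists passed in edgeR's test, over all miRNAs or over the list alone. Across all miRNAs tested, 129 had an unadjusted p under 0.05 in limma-voom and 93 in DESeq2, against 65 higher and 64 lower in edgeR. The let-7 median ratio was -0.05 in jejunum and -0.02 in colon, turning in colon to 0.35 with library totals alone, 0.07 with median-of-ratios factors and 0.06 with the authors' factors; at 100 CPM the medians were 0.09 and 0.18 and with no filter 0.00 and 0.18. let-7f-5p had a log2 change of 0.41 (adjusted p = 0.0968) and let-7c-5p of -0.35 (adjusted p = 0.118). The miR-17-92 median was -0.47 in jejunum and -0.02 in colon, turning in colon to 0.26 with library totals alone and 0.04 with median-of-ratios or the authors' factors. The miR-29 medians of 0.57 and 0.49 turned to -0.11 and -0.31 scaled to mappable reads and to -0.56 and -0.95 at 100 CPM, where the 1 member left was the abundant miR-29a-3p. The miR-181 medians of 0.25 and 0.17 turned to -0.52 and -0.69 scaled to mappable reads and to -0.03 and -0.14 at 100 CPM, and the miR-30 medians of 0.55 and 0.18 turned to -0.27 and -0.73 scaled to mappable reads. The medians of miR-34 and miR-449 were -0.13 and -0.74, the latter 0.02 with no filter. Erythroid medians were 0.81 in jejunum, or -1.03 with no filter, and 0.18 in colon, or -0.61 scaled to mappable reads; endothelial medians were -0.22 and 0.12, the latter -0.79 scaled to mappable reads. Neuronal and glial medians were 0.01 in jejunum, or -0.78 scaled to mappable reads and -0.11 with the authors' factors, and -0.46 in colon, or 0.80 at 100 CPM. Sfmbt2 medians were -0.51 in jejunum, or -0.34 at the bound and 0.01 with no filter, and 0.29 in colon, or -0.56 scaled to mappable reads. Of 10 insulin and lipid metabolism arms 1 fell, the hepatocyte miR-122-5p, also 1 over the list alone; the medians were 0.13 in jejunum, or -0.62 scaled to mappable reads, and -0.32 in colon, or 0.04 with library totals alone.

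**Figure D2:**
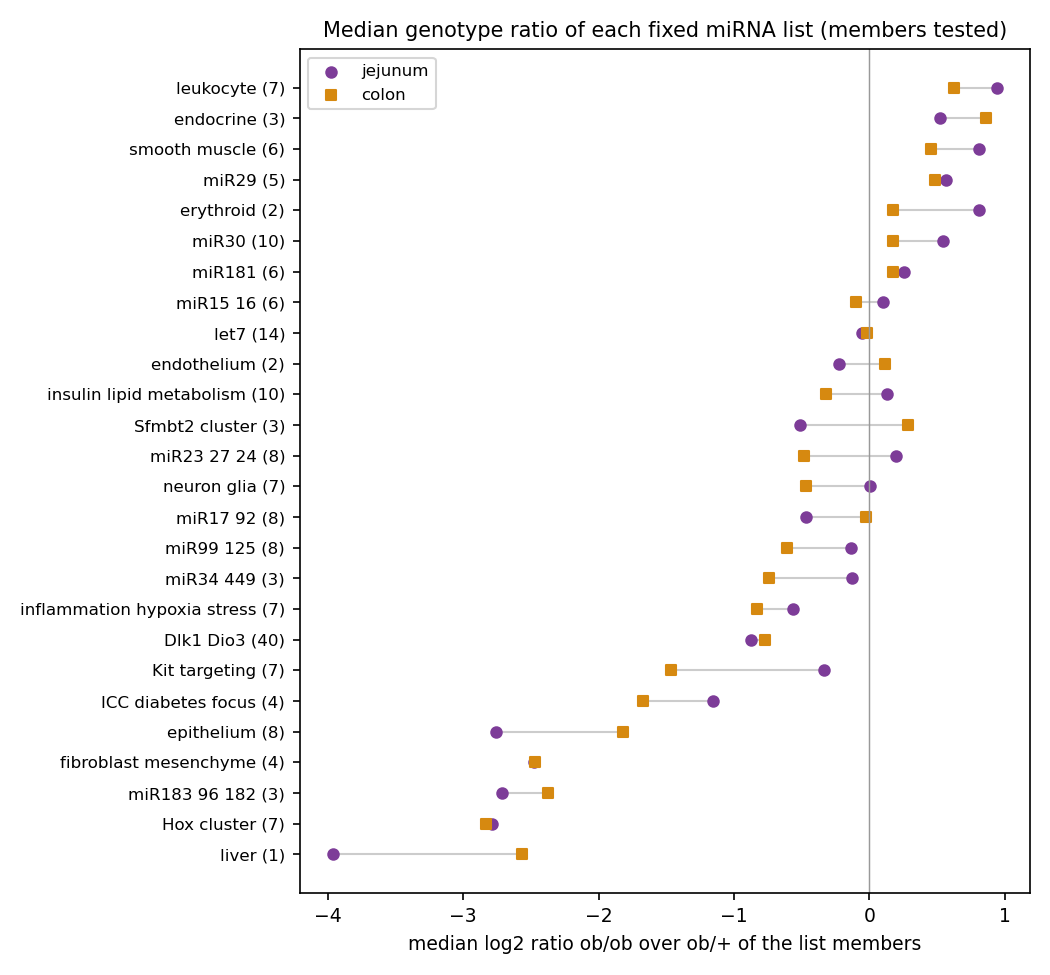
Median log2 ratio of ob/ob over ob/+ of the members of each of the 26 lists fixed beforehand, in jejunum (circles) and colon (squares), with the number of members tested in brackets. The Hox list includes the miR-10 arms. It lies at -2.79 in jejunum and -2.83 in colon, or 0.00 and -0.22 with no abundance filter. The fibroblast list lies at -2.48 and -2.47, while the muscle list lies at 0.81 and 0.45, turning to -0.01 and -0.47 scaled to mappable reads.

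These changes come from edgeR's quasi-likelihood test, in which the 2 tissues stand in for replicates. A miRNA's genotype effect is weighed against a spread that combines 2 sources. They are its own difference of that effect between jejunum and colon (1 residual degree of freedom) and a spread estimated across miRNAs (3.70 prior degrees of freedom). Of 322 miRNAs tested, 24 rose and 33 fell at an adjusted p under 0.05. With other settings the counts were 37 and 27 (library totals alone), 59 and 56 (median-of-ratios factors), 56 and 67 (the authors' factors), 19 and 158 (scaled to mappable reads), 58 and 49 (without hairpin entries), 41 and 44 (no tissue term), 13 and 21 (limma-voom), and 0 and 2 (no abundance filter, leaving miR-10b-5p and miR-196b-5p). Of the called miRNAs named here, limma-voom also lost miR-615-3p and miR-183-5p (adjusted p = 0.0616 for each, ranges over the alternatives 6.68e-08 to 0.138 and 1.10e-10 to 0.0836). Others it lost include miR-182-5p (0.0640, 1.14e-10 to 0.142), miR-450a-5p (0.0532, 3.90e-06 to 0.125) and miR-200c-3p (0.0532, 1.56e-10 to 0.122). The calls of miR-322-3p and miR-322-5p were lost in limma-voom too (adjusted p = 0.0616 and 0.0704). The adjusted p ranges given cover the 10 alternative fits to all 4 libraries. With 1 library left out, a test was possible only without a term for the other factor, where the lone library is taken to vary like the others. Without the ob/+ jejunum library 50 rose and 38 fell, and without the ob/+ colon library 28 and 44. Without either ob/ob library 0 rose and 2 fell, miR-10b-5p and miR-196b-5p (adjusted p = 0.0155 for each without jejunum and 0.0159 for each without colon), so that in this fit no other call held without each library. All 57 kept their sign, and at least 54 stayed at least 2-fold different. The 57 were selected in these same libraries, most of which each such fit reuses, so this is no independent check. Without each ob/ob library 55 calls were lost, of which 6 moved by over 1.5 times, 3 of them towards no change. Thus miR-199a-5p lost its call at -2.43 and -2.33 (adjusted p = 0.0589 and 0.0673). The labels do not say whether both tissues came from the same mice and name no batch, so the p-values measure only the spread between these libraries, which may be technical.

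Within jejunum, 47 miRNAs were at least 2-fold higher in ob/ob, 58 at least 2-fold lower and 217 in between. Among miRNAs reaching 100 CPM the highest log2 ratios were those of miR-615-3p (3.44, counting interval 2.53 to 5.88), miR-351-3p (2.89, 2.13 to 4.32) and miR-503-3p (2.88, 2.31 to 3.74). miR-708-5p was also higher (2.15, 1.69 to 2.75). The lowest were those of miR-196b-5p (-7.19, -9.26 to -6.41), miR-200b-3p (-4.75, -6.16 to -4.07), miR-196a-5p (-4.48, -5.53 to -3.88) and miR-122-5p (-3.96, -5.28 to -3.28). miR-10b-5p stood at -3.55 (-3.59 to -3.51). Its ratio in the authors' deposited table, which is a plain quotient and not on the log2 scale, was 0.0786 in jejunum and 0.0552 in colon. Of the 2-fold differences in jejunum 44.8% were higher, against 12.3% (19 higher and 135 lower) scaled to mappable reads.

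Within colon, 55 miRNAs were at least 2-fold higher in ob/ob, 56 at least 2-fold lower and 211 in between. Among miRNAs reaching 100 CPM miR-3963 had the highest log2 ratio (2.88, counting interval 2.27 to 4.02), followed by miR-351-3p (2.75, 2.15 to 3.81), mir-3470b (2.63, 2.06 to 3.60) and mir-1954 (2.53, 2.09 to 3.17). The lowest were miR-196b-5p (-6.28, -7.52 to -5.58), miR-10b-5p (-4.26, -4.31 to -4.21), miR-10b-3p (-3.12, -4.29 to -2.40) and miR-214-3p (-2.87, -4.05 to -2.15). miR-199a-5p stood at -2.44 (-2.72 to -2.19). Of the 2-fold differences in colon 49.5% were higher, against 65.2% with library totals alone, which shifted the median ratio by 0.35, and 12.1% (23 higher and 167 lower) scaled to mappable reads.

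Whether leptin deficiency had like effects in jejunum and colon was described by the genotype ratios of the 2 tissues, which share no library. miR-10b-5p and miR-196b-5p were lower and miR-351-3p and miR-503-3p higher in both. Of 322 miRNAs 253 (78.6%) had ratios of the same sign, 32 were at least 2-fold higher and 35 at least 2-fold lower in both tissues, and 0 differed at least 2-fold in opposite directions. The ratios of 65 of the 322 differed at least 2-fold between the tissues. Across miRNAs, which are not independent replicates, the ratios had a Pearson correlation of 0.796 and a Spearman correlation of 0.759. The difference between tissues had no residual degrees of freedom and was not tested; it was -0.71 for miR-10b-5p and 0.91 for miR-196b-5p (colon minus jejunum, log2).

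**Figure D3:**
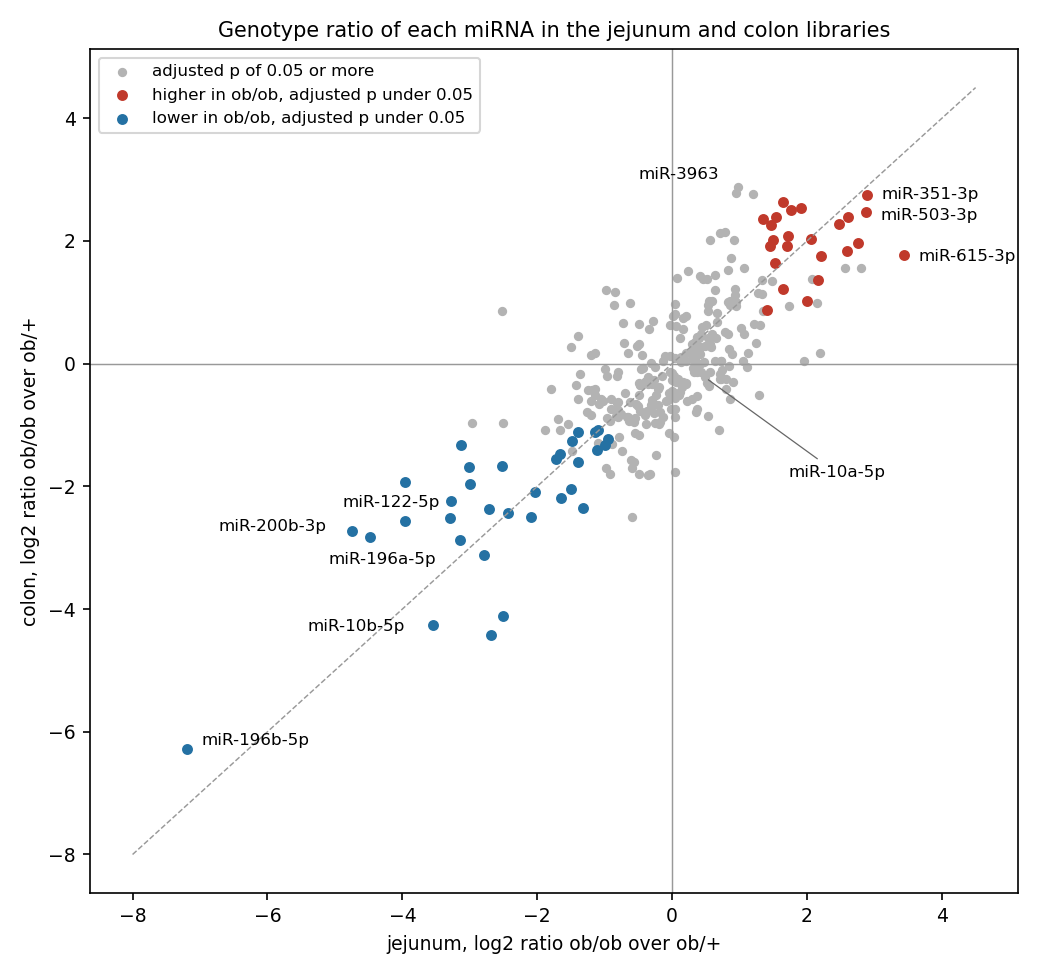
Log2 ratio of ob/ob over ob/+ in jejunum (x axis) against colon (y axis) for the 322 miRNAs tested, 1 point each, with a dashed line at equal ratios. Coloured points are the 24 miRNAs that rose and the 33 that fell over both tissues at an adjusted p under 0.05, with miR-196b-5p at -7.19 and -6.28 and miR-351-3p at 2.89 and 2.75.

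How jejunal and colonic ICC differ was the other comparison of the design. By value, miR-215-5p, an intestinal epithelial miRNA, was lower in colon in both genotypes (log2 ratio of colon over jejunum -1.47 in ob/+ and -0.80 in ob/ob), as was miR-194-5p (-1.12 and -0.54). The muscle miRNAs miR-133a-3p (-0.34 and -0.69) and miR-145a-5p (-0.39 and -0.53) were also lower in colon. miR-34c-5p (0.39 and 0.56) and miR-181b-5p (0.48 and 0.37) were higher in colon. These miRNAs were picked because they differed in the same direction in both genotypes. Across the 322 miRNAs tested, the tissue ratios of ob/+ and ob/ob had a Pearson correlation of 0.043 and a Spearman correlation of -0.018. miR-10b-5p had a ratio of 0.09 in ob/+ (counting interval 0.08 to 0.11) and -0.62 in ob/ob (-0.68 to -0.55). In edgeR's test 0 miRNAs passed, with a smallest adjusted p of 0.896; at an unadjusted p under 0.05, 1 was higher and 13 lower in colon. Fits with 1 library left out had no genotype term, so the genotype difference counted as spread. They could not decide whether jejunum and colon differ. DESeq2 and limma-voom called 0 and had 7 and 14 with an unadjusted p under 0.05. miR-183-5p and miR-96-5p, named after their values were seen, were called lower in colon by edgeR in some alternatives. The adjusted p of each was 0.0315 with median-of-ratios factors, 0.0407 with the authors' factors and 0.0190 without hairpin entries. In colon miR-96-5p had only 12 counts in ob/+ and 0 in ob/ob. Adjusted over the list alone, 2 of the 3 miRNAs of the cluster of miR-183, miR-96 and miR-182 passed as lower in colon, and 0 in the other lists. On simulated data the test recovered 3 of 27 miRNAs changed 2-fold, 12 of 22 changed 4-fold and 25 of 29 changed 8-fold.

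In ob/+ mice 12 miRNAs were at least 2-fold higher and 26 lower in colon, and in ob/ob mice 16 and 9. The share of higher among them was 31.6% in ob/+ and 64.0% in ob/ob, against 16.1% and 75.0% with library totals alone. In ob/+ it was 20.0% with median-of-ratios or the authors' factors and 47.4% scaled to mappable reads. Log2 CPM correlated across miRNAs at 0.980 between the tissues in ob/+ and 0.982 in ob/ob, against 0.907 between the genotypes in jejunum and 0.914 in colon.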

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

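The test reported in this part was chosen after the result was seen. miR-10a-5p had a positive genotype ratio in jejunum (log2 0.49) and a negative one in colon (-0.22), with counting intervals that exclude 0 in both; the difference, colon minus jejunum, was -0.71. The same opposite signs were seen for miR-24-3p (difference -0.57), miR-26b-5p (-0.52), miR-378a-3p (-0.46), miR-143-3p (-0.37) and miR-125a-5p (-0.33). None of these differences was tested, since 1 library per group leaves no spread to test against, and the colon ratios of miR-10a-5p, miR-26b-5p, miR-378a-3p, miR-143-3p and miR-125a-5p turned positive with library totals alone. The colon ratio of miR-143-3p also turned positive with median-of-ratios or the authors' factors. Scaled to mappable reads, the jejunum ratios of all 6 turned negative (-0.33 for miR-10a-5p), and with the authors' factors those of miR-24-3p and miR-125a-5p did.

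Most mappable reads lay outside miRNAs, and more so in ob/ob: 87.7% in jejunum and 89.4% in colon, against 77.5% and 73.7% in ob/+. More fragments of other RNA might also raise entries that are not true miRNAs, such as mir-6240 or miR-3470b, among the 17 higher in ob/ob outside the X-linked cluster. Counted per mappable read outside miRNAs, those entries still had a median log2 change of 0.73 in jejunum (SD over entries 0.80) and 1.19 in colon (SD 0.71). The jejunum median is smaller than its spread, so this explanation stays open for these entries. A genotype effect on the miRNAs themselves is open as well.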

How the results depend on the processing

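Some alternatives (mappable reads, the authors' factors, no hairpin entries, 1 library left out) were chosen after the data were seen. Among the named miRNAs and the lists, no ratio of at least 2-fold reversed its sign. For single miRNAs this says little, since the largest median shift with any scaling (-0.86 in colon, log2) was smaller than a 2-fold ratio. Ratios under 2-fold did turn, as given above and below. Of the 57 genotype calls, 57 were kept with median-of-ratios factors and with the authors' factors, 56 with no tissue term, 52 without hairpin entries, 50 scaled to mappable reads, 48 with library totals, 44 in DESeq2, 34 in limma-voom, 31 at 100 CPM, where fewer miRNAs are tested, and 2 with no filter, all in the same direction. Calls higher numbered 37 with library totals, 59 with median-of-ratios factors (56 lower), 56 with the authors' factors (67 lower), 58 without hairpin entries, 41 with no tissue term, 13 in limma-voom (21 lower) and 0 with no filter (2 lower); 158 were lower scaled to mappable reads. The tissue test gave 2 lower with median-of-ratios factors, the authors' factors or no hairpin entries. The causes were not tested.

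Counts of 2-fold differences, higher and lower, moved with the set tested or the threshold. With no filter they were 116 and 117 in jejunum, 106 and 92 in colon, 24 and 67 between tissues in ob/+ and 59 and 69 in ob/ob. At 100 CPM they were 18 and 21, 15 and 27, 1 and 6, and 2 and 0, with 122 miRNAs of the same direction in both tissues. At 1.5-fold they were 85 and 94, 83 and 106, 35 and 56, and 41 and 56, and at 4-fold 15 and 23, 20 and 19, 0 and 3, and 2 and 1. Scaled to mappable reads they were 19 and 135 in jejunum and 23 and 167 in colon. Between tissues in ob/+, 5 were higher with library totals, 7 with median-of-ratios or the authors' factors and 1 with a prior count of 5. In ob/ob 17 were lower with a prior count of 0.5, and 4 were higher and 4 lower with a prior count of 5. The median ratio shifted by 0.27 between tissues in ob/ob with library totals, by 0.18 in ob/+ scaled to mappable reads, by -0.12 in jejunum and 0.12 between tissues in ob/ob with the authors' factors, and in colon by 0.10 without hairpin entries and 0.21 with no filter. With no filter the colon median of the Kit-targeting list went from -1.47 to 0.00 and that of the Hox list from -2.83 to -0.22, and the jejunum medians of the Hox list went from -2.79 to 0.00, of the epithelial list from -2.76 to -1.03, of the muscle list from 0.81 to 0.17 and of the erythroid list from 0.81 to -1.03. At 100 CPM the colon median of the neuronal and glial list went from -0.46 to 0.80. Of the single ratios of named miRNAs 173 moved beyond their counting interval scaled to mappable reads, 62 with library totals, 39 with the authors' factors and 19 with median-of-ratios factors. Leaving out 1 library leaves the fit with both terms 0 residual degrees of freedom and no test. With no term for the other factor, genotype calls then numbered from 0 to 50 higher and from 2 to 44 lower, and tissue calls 0; 54 of the 57 were kept without the ob/+ jejunum library, 52 without the ob/+ colon library and 2 without either ob/ob library, in the same direction. The tissue fits among these counted the genotype difference as spread, so they could not decide whether the tissues differ. No paired analysis was possible because each group holds 1 library and the labels pair none by mouse or replicate, beyond the tissue term, which compares the genotypes within each tissue. Depth limits entries under about 10 CPM, where 1 count is worth up to 3.15 CPM.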

Other observations

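The tests of clusters, arms, read assignment, cell sources and X-linked entries were chosen after results were seen; after a first run the epithelial test was replaced, and the X-linked test's criterion was reworded with the same outcome. Among miRNAs outside the lists, named after their values were seen, miR-335-3p fell by 1.40 ± 0.26 on the log2 scale (edgeR adjusted p = 0.0336), miR-204-5p by 1.29 ± 0.28 (adjusted p = 0.0414) and miR-151-3p by 1.17 ± 0.24 (adjusted p = 0.0393). miR-184-3p fell by 2.52 ± 0.48 (adjusted p = 0.0344) on 27 counts or fewer in a library. DESeq2 did not call miR-204-5p (adjusted p = 0.0747, range over the alternatives 1.31e-07 to 0.147) or miR-184-3p (0.153, 6.14e-06 to 0.153), and limma-voom did not call miR-151-3p (0.0532, 3.59e-09 to 0.145).

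miRNAs of 1 genomic cluster may change together. Over 24 clusters with 87 hairpins the SD of the genotype log2 change within clusters was 0.563, against a median of 1.30 with shuffled clusters (one-sided permutation p = 1e-05, the smallest the shuffles can give). Without the X-linked cluster it was 0.569 against 1.07 over 23 clusters (permutation p = 1e-05). The arms of 57 hairpins had a Pearson correlation of 0.765 and a Spearman correlation of 0.646 across hairpins, which are not independent replicates (permutation p = 1e-05), and 0.699 without the 2 farthest hairpins; 38 had the same sign. These values speak for changes at the level of transcripts, but a difference between cell pools would move clusters and arms together too.

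The fall of miR-10b, miR-196a and miR-196b could come from reads assigned to miR-10a or from other cells in the ob/+ sorts. A move to miR-10a of all the reads lost by miR-10b is argued against. The summed CPM of miR-10a-5p and miR-10b-5p still changed by -0.80 in jejunum and -1.52 in colon (log2). These sums cannot decide whether part of the reads moved. Epithelial cells are argued against for miR-10b, which held 148 and 384 times the counts of the miR-200 family in the ob/+ libraries, though the family fell with it, and stay open for miR-196 (2.93 and 7.58 times); an earlier version, the ratio to that family in colon over jejunum (2.59 for miR-10b-5p and 1.84 for miR-196a-5p), had argued against both and was dropped because the epithelia of the tissues can differ. Fibroblast-like cells stay open: the summed miR-199 and miR-214 changed by -2.32 and -2.49, while the ratio of the 4 arms to that sum in ob/ob was a median of 0.359 times that in ob/+, from 0.0250 (miR-196b-5p, jejunum) to 0.757 (miR-196a-5p, colon), and such cells in ob/ob could differ from those in ob/+. Leptin deficiency itself remains open and was not tested further.

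The X-linked cluster, which was higher in ob/ob, might reflect more X chromosome copies, as with more females in the ob/ob pools. The other 22 X-linked entries had a median log2 change of -0.24 in jejunum (SD 0.88) and -0.39 in colon (SD 0.98), with 1 called higher and 3 lower. The cluster's medians were 2.48 and 1.76. These values argue against a rise shared by X-linked miRNAs. They cannot decide whether the pools differed in sex, since female cells silence 1 X chromosome. A regulated transcript or a difference in the cell mix of the pools stays open and was not tested.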
